A study of Mus musculus with 18 samples.

How the data were processed

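The samples were 18 liver libraries of wild-type C57BL/6J mice, 3 for each of 6 groups that combine the LF or HF diet with no further treatment, CR or Ex. Per the labels, livers were flash frozen, RNA was extracted with Trizol and enriched for polyA RNA, and Illumina libraries were prepared. The deposited values are RPKM per RefSeq transcript. Per the submitters' processing notes the authors used TopHat 1.4.1 and Cufflinks 1.3.0 with the mm10 genome, and neither the annotation version nor the read total behind the scaling is stated. No counts were used here and no reads were processed. The per-sample values and the series-wide table held the same 550476 values. Groups and replicate numbers were taken from the sample titles. An exact 0 beside high values in other libraries, as for Alb, is kept as deposited and may be a failed estimate and not an absence.

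Of 30582 RefSeq rows, 29999 were named through a RefSeq table for GRCm38.p6 and 184 through GENCODE, and 399 kept their identifier. Of the 23532 resulting genes 4218 had more than 1 row, and the row with the highest mean over the 18 libraries stood for the gene. Genes with at least 1 RPKM in at least 3 of the 18 libraries were kept, which left 10356. Depth per library was estimated from the step between the lowest nonzero values of genes with 1 row of 1000 to 4000 bp, with 467 to 732 genes used per library. It is an estimate, and no counting interval was computed from it. RPKM sums per library ran from 512495 in LF+Ex 3 to 589042 in HF 1, and the 10 most abundant RefSeq rows took 21.3% to 29.4% of them. The highest shares, 27.2% to 29.4%, were those of HF 1 and HF+Ex 1, 2 and 3, the libraries where Alb was above 0.

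Values were analysed as log2(RPKM + 1) with no further scaling in R 4.3.3 with limma 3.58.1, as 1 model with a mean for each of the 6 groups, 12 residual degrees of freedom and an intensity trend in the moderated variance. The tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes kept. The 7 comparisons of 2 groups and the 2 interactions, of CR and of Ex with diet, are contrasts of this model. Every adjusted p of a gene in the report comes from limma. The model, the filter, the comparisons, the gene lists and the alternatives were fixed before the data were examined, except for the settings named as chosen after seeing the data.

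Of 34 gene lists written from textbook knowledge, 30 had at least 5 tested members. They were tested with camera from limma at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Alternatives were camera with an estimated correlation and fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes. Members were also counted by the gene test over all genes and adjusted over the list alone. With an estimated correlation the calls that held were the male-biased and female-biased lists in the CR by diet interaction, the female-biased list in HF+CR against LF+CR and the male-biased list in LF+Ex against LF, the last not called by fry.

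The genes named follow a rule written beforehand. For each comparison it takes up to 8 genes with the largest positive and up to 8 with the largest negative difference among called genes whose groups do not overlap and whose mean is at least 2 RPKM in 1 group, without predicted genes, and up to 4 called members of each list that passes camera, in its direction. It adds 18 genes reported whatever their result in HF against LF and in both CR comparisons, of which Dnmt3b was not among the genes tested. For each interaction it takes up to 8 called genes with the smallest adjusted p, and the 5 smallest p where none passes. With 3 against 3 libraries, 10% of genes have groups that do not overlap by chance. Results for some genes that meet this rule are not reported here. Gene positions are RefSeq gene spans on GRCm38.p6.

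The diet difference kept under CR or Ex was a slope through the origin over the genes called in HF against LF, with a jackknife error over the 6 libraries of the dependent comparison. The 2 slopes were compared by an exact permutation of the CR and Ex labels within each diet, with 400 assignments. The tests were tested on simulated data: of 50 genes per level changed in LF+CR against LF, 46%, 76%, 92% and 98% were recovered at 1.5, 2, 3 and 4-fold. These folds are of RPKM + 1. At low RPKM the same fold of RPKM is a smaller step, so its recovery would be lower. Of the genes left unchanged in that comparison 3 were called. In HF against LF, HF+Ex against HF and the Ex by diet interaction, simulated without any change, 0 genes were called. The simulated genes varied independently, with the same spread in all groups, whereas genes of a list are correlated in the real data.

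Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 RPKM, median-of-ratios scaling, quantile normalization, variance moderation without trend or with robust estimation, array weights, the compared groups fitted alone, a replicate block, transcripts summed per gene, the series-wide table and each library left out in turn. Settings chosen after seeing the data left out Alb, genes at 0 in at least 3 libraries and at 1 RPKM or more in all others, the libraries with pancreas transcripts, the libraries with raised bile duct markers, and Cyp2b13 with Cyp4a12b for the slopes. Figures were drawn with matplotlib 3.10.9.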

Results

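PolyA RNA of whole liver from wild-type C57BL/6J mice was sequenced in 18 libraries, 3 for each of 6 groups named LF, LF+CR, LF+Ex, HF, HF+CR and HF+Ex. Treatment began at 5 weeks of age and liver was taken at 62 weeks. LF, HF, CR and Ex are read here as low-fat diet, high-fat diet, caloric restriction and exercise from knowledge of such studies, since the labels give the abbreviations alone. The labels state neither the sex of the mice nor that each library came from 1 animal, so the p-values measure only the spread between these samples. The deposited unit is RPKM, reads scaled to transcript length and library size, without counts, so the depth is not known. Steps among the lowest values gave an estimate of 21.2 M reads in LF 3 to 40.7 M in LF+CR 2, with a median of 25.2 M. Each library held 9069 to 9997 genes at 1 RPKM or more, and 10356 genes were tested. Group levels are means ± SD over n = 3 libraries, and differences are of log2(RPKM + 1) ± SE from limma. Gene lists were tested with camera.

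Transcripts of pancreatic enzymes were present in 3 of the liver libraries. Prss2, a trypsinogen, was at 261 RPKM in LF+CR 1, 35.4 RPKM in HF+CR 1 and 5.92 RPKM in LF+Ex 1, and at most 0.457 RPKM in the other 15 libraries. Ctrb1, a chymotrypsinogen, was at 615, 64.5 and 7.32 RPKM in these libraries and at most 1.34 RPKM elsewhere. Cholangiocyte markers, genes of bile duct cells, were highest in HF+CR 3 and LF 2, where their mean lay 1.33 and 0.98 above the mean of the 18 libraries on the log2 scale. Every count below was repeated without LF+CR 1, LF+Ex 1 and HF+CR 1 (the pancreas libraries), and again without LF 2 and HF+CR 3 (the bile duct libraries), as settings chosen after seeing the data. The name bile duct library is a short label and does not give every trait of HF+CR 3. HF+CR 3 was also the highest library for stellate cell genes (1.03), lymphocyte markers (0.91), antioxidant genes (0.74), cell cycle genes (0.52) and immediate early genes (0.47). Across genes, libraries of 1 group correlated at r = 0.952 to 0.989 and libraries of different groups at r = 0.928 to 0.986. Some transcripts of close paralogs share reads, so the split within Mup, Saa1 and Saa2, Cyp2b9 and Cyp2b13, Cyp4a12a and Cyp4a12b, other Cyp2a, Cyp2c and Cyp4a genes, Acot, Slc22a26 to Slc22a28, Serpina1, pancreatic trypsin and class II H2 genes is uncertain.

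**Figure D1:**
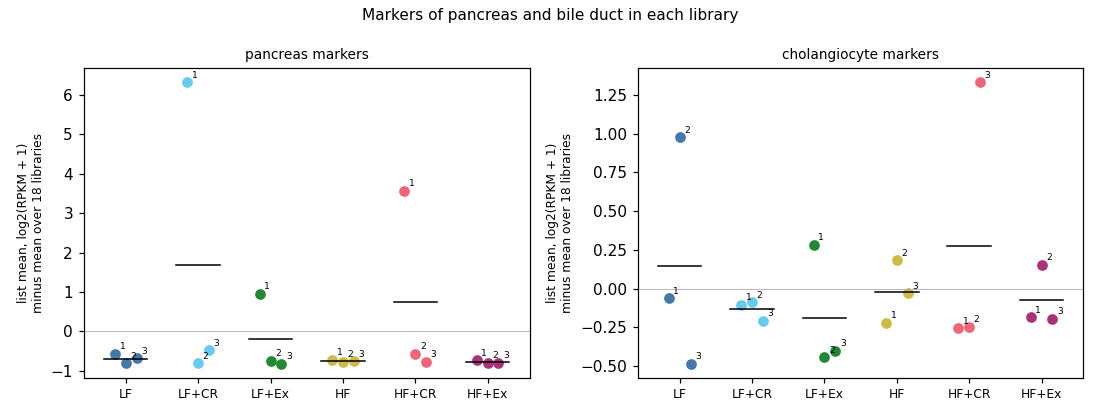
Mean log2(RPKM + 1) of the tested pancreas markers and cholangiocyte markers in each library, minus the mean over the 18 libraries, by group; points are libraries numbered 1 to 3 and black lines are group means. Pancreas markers stood at 6.32 in LF+CR 1, 3.57 in HF+CR 1 and 0.96 in LF+Ex 1, and cholangiocyte markers at 1.33 in HF+CR 3 and 0.98 in LF 2.

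HF was compared with LF to ask how the HF diet alone changed the liver. Of 26 acute-phase genes 1 was called, Orm3, and of 27 interferon-response genes 1, Cxcl9, both higher. Orm3, an acute-phase orosomucoid, rose from 0.317 ± 0.380 to 7.61 ± 3.49 RPKM, and Cxcl9, an interferon-induced chemokine, rose from 1.96 ± 0.852 to 9.66 ± 4.25 RPKM. Cyp2b13, a cytochrome P450 more abundant in female mouse liver, rose from 0.438 ± 0.371 to 11.8 ± 6.20 RPKM, and Cyp4a12b, more abundant in male liver, fell from 16.1 ± 13 to 1.47 ± 1.82 RPKM. The lists of sex-biased genes were not called by camera, with medians of -0.14 for female-biased (adjusted p = 0.997) and -0.23 for male-biased genes (0.136). Srd5a1, a steroid 5-alpha reductase, fell from 31.6 ± 4.59 to 14.9 ± 0.732 RPKM. limma called 42 genes at a Benjamini-Hochberg adjusted p under 0.05, 27 higher and 15 lower, against 1742 genes at an unadjusted p under 0.05. Log2 differences were 3.06 ± 0.40 for Cyp2b13 (adjusted p = 0.0140), 2.67 ± 0.41 for Orm3 (0.0192), 1.81 ± 0.35 for Cxcl9 (0.0405) and -2.78 ± 0.55 for Cyp4a12b (0.0455). Ear2, Tgtp1, Cebpzos, Postn and Samd9l also rose, by log2 differences of 1.04 to 1.65, and Zfpm1, Rab43, Fbxo21, Eif4ebp2, Cnot6l and Brwd1 fell, with log2 differences of -0.91 to -0.58.

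Of 27 interferon-response genes, 1 passed over all genes and 8 adjusted over the list alone, all higher, with a median log2 difference of 0.58 (camera adjusted p = 5.80e-10; adjusted p = 0.998 with an estimated correlation). None of 6 class II antigen presentation genes passed over all genes and 6 passed adjusted over the list alone, with a median of 1.17 (0.000167; adjusted p = 0.998 with an estimated correlation). Acute-phase genes had a median of 0.24 (camera adjusted p = 0.0284; adjusted p = 0.998 with an estimated correlation), with 1 of 26 higher over all genes and 5 higher and 1 lower adjusted over the list alone. Macrophage markers had a median of 0.58 (0.0284; adjusted p = 0.998 with an estimated correlation), with no member called over all genes and only Cd163, which was lower (-1.32), passing adjusted over the list alone. Cholesterol synthesis and uptake genes had a median of 0.32 with 0 of 25 called over all genes and 1 adjusted over the list alone (0.000993; adjusted p = 0.998 with an estimated correlation), a camera call that was lost without the bile duct libraries (0.222). Camera also called lymphocyte markers higher, and chromatin modifiers, fatty acid oxidation genes, ribosomal proteins and heat-shock proteins lower, with medians of 0.47, -0.12, -0.11, -0.14 and -0.23, no member called over all genes and, adjusted over the list alone, 1 chromatin modifier and 3 fatty acid oxidation genes lower. With an estimated correlation all 10 lists called in this comparison had an adjusted p of 0.998. The genes reported whatever their result did not pass: log2 differences were -0.66 for Scd1, 0.44 for Fasn, 1.08 for Sqle, -0.69 for Pck1, -1.29 for Cyp4a14, 1.5 for Cidec, -0.50 for Pparg, 0.48 for Cyp2b9 and 1.85 for Saa1. They lay between -0.18 and 0.25 for Cyp7a1, G6pc, Cd36, Cyp3a11, Hspa5, Per2 and Sirt1.

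Without the pancreas libraries 11 genes passed. These libraries belong to neither HF nor LF, and the median difference of all genes was -0.0195 with and without them. The fall thus came from the estimate of spread shared by all groups and not from the differences. The same holds for every other library outside HF and LF. Without the bile duct libraries, of which LF 2 is an LF library, 140 genes passed, 125 higher and 15 lower. Without LF 2 the count was 30, 28 higher and 2 lower. The count moved by over 1.5 times when any of these libraries was left out: 0 without LF 1, 10, 4 and 8 without HF 1, HF 2 and HF 3 (the last 8 higher and 0 lower), 26, 16 and 25 without LF+CR 1, 2 and 3, 24 and 91 without LF+Ex 2 and 3 (the last 45 higher and 46 lower), 26, 21 and 79 without HF+CR 1, 2 and 3, and 27 and 15 without HF+Ex 2 and 3. Median-of-ratios scaling gave 203 genes with 53.2% higher and quantile normalization 283 with 45.2% higher, against 64.3% of the deposited values, while a pseudocount of 0.1 gave 21 genes, a mean of at least 5 RPKM 14 and the HF and LF libraries alone 0. With the replicate block 14 genes passed, 11 higher and 3 lower.

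LF+CR was compared with LF to ask what CR did on the LF diet. The called genes included 16 of cholesterol synthesis and uptake and 9 of fatty acid synthesis that rose, and 14 of fatty acid oxidation and 5 of lipid droplets that fell. Insig1 and Lss of the cholesterol list rose from 37.2 ± 13.6 to 164 ± 26.5 RPKM and from 4.88 ± 1.09 to 16.4 ± 2.75 RPKM. Fasn, the fatty acid synthase, rose from 26.9 ± 14.4 to 209 ± 110.2 RPKM. Of genes known to be higher in female mouse liver 9 of 21 rose, and of those known to be higher in male liver 13 of 26 fell: Cux2, a transcription factor of female liver, rose from 0.220 ± 0.210 to 6.84 ± 2.21 RPKM, and the major urinary protein gene Mup20 fell from 8191 ± 3172 to 297 ± 180.2 RPKM. limma called 673 genes at an adjusted p under 0.05, 312 higher and 361 lower, with 2316 at an unadjusted p under 0.05.

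Among 25 genes of cholesterol synthesis and uptake, 16 rose over all genes and 19 adjusted over the list alone, with a median log2 difference of 1.28 (camera adjusted p = 1.30e-15; adjusted p = 0.223 with an estimated correlation). Insig1 differed by 2.18 ± 0.33 (adjusted p = 0.00170) and Lss by 1.57 ± 0.26 (0.00313), and Sqle also rose, by 2.08 (0.0152). Of 25 fatty acid synthesis genes 9 rose over all genes and 15 adjusted over the list alone, with a median of 0.97 (5.72e-10; adjusted p = 0.223 with an estimated correlation). Fasn rose by 2.87, Acly by 2.18, Pnpla3 by 1.82 and Acaca by 1.49. Of 35 genes of fatty acid oxidation and PPAR alpha targets 14 fell over all genes and 21 adjusted over the list alone, with a median of -0.55 (5.00e-13; adjusted p = 0.223 with an estimated correlation). They included Vnn1 (-2.38), Cyp4a32 (-1.35), Acaa1a (-0.84) and Eci1 (-0.79). Of 20 lipid droplet genes 5 fell over all genes and 10 adjusted over the list alone, with a median of -0.70 (0.000122; adjusted p = 0.375 with an estimated correlation). Cidec, a lipid droplet fusion protein, fell from 25.4 ± 15.1 to 1.5 ± 0.117 RPKM, and Fitm1, Fitm2 and G0s2 differed by -2.19, -1.05 and -1.95.

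**Figure D2:**
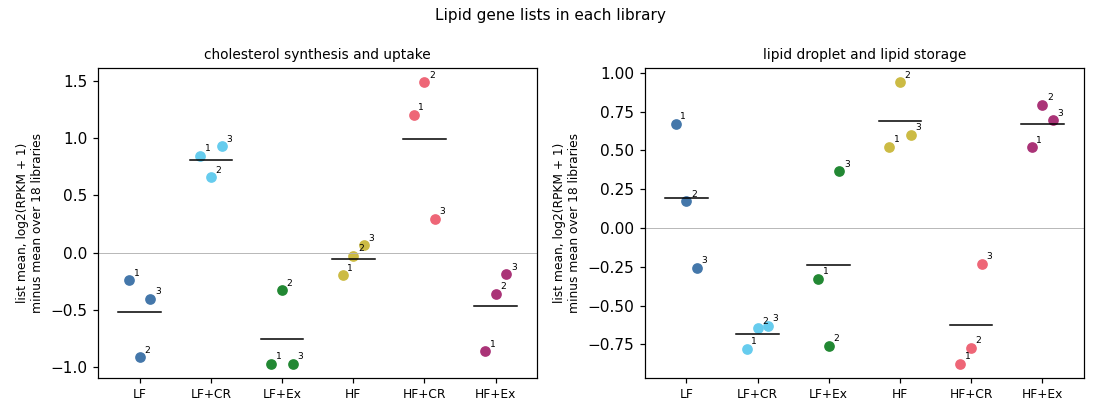
Mean log2(RPKM + 1) of the tested genes of cholesterol synthesis and uptake and of lipid droplets and lipid storage in each library, minus the mean over the 18 libraries, by group; points are libraries numbered 1 to 3 and black lines are group means. Cholesterol genes lay between 0.66 and 0.93 in LF+CR and between -0.92 and -0.24 in LF, and lipid droplet genes lay between -0.88 and -0.23 in HF+CR and between 0.52 and 0.94 in HF.

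Sex-biased genes made up several of the largest differences. Of 26 male-biased liver genes 13 fell over all genes and 15 adjusted over the list alone, with a median of -1.63 (camera adjusted p = 5.37e-13; adjusted p = 0.223 with an estimated correlation). Mup20 (NM_001012323, chromosome 4, 62011337 to 62054143, as RefSeq gene spans on GRCm38.p6) differed by -4.86 ± 0.44 (adjusted p = 2.53e-05), C8a, a complement component, by -3.88 ± 0.30 (7.61e-06), and Cyp4a12a by -4.68 ± 0.54 (0.000242). Elovl3, Mup21, Slco1a1 and Cyp4a12b fell as well, with log2 differences of -4.56 to -3.32. Of 21 female-biased genes 9 rose over all genes and 11 adjusted over the list alone, with a median of 1.43 (2.75e-10; adjusted p = 0.0606 with an estimated correlation). Cyp2b13 (NM_007813, chromosome 7, 26061388 to 26096197) differed by 4.48 ± 0.40 (adjusted p = 2.53e-05), Cux2 by 2.65 ± 0.18 (1.45e-06), and Slc22a26 by 2.45 ± 0.24 (8.61e-05). With the pancreas libraries left out, 7 male-biased and 7 female-biased genes and 7 of the cholesterol list passed over all genes. The differences remained without LF+CR 1. In LF+CR 2 and 3 the male-biased means were -1.82 and -1.62 (LF -0.365 to 0.75) and the female-biased means 1.43 and 1.55 (LF -0.06 to 0.24). The cholesterol means were 0.66 and 0.93 (LF -0.92 to -0.24).

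Amino acid catabolism genes rose for 8 of 32 over all genes, and for 12 with 1 lower adjusted over the list alone, with a median of 0.30 (camera adjusted p = 1.88e-05; adjusted p = 0.386 with an estimated correlation). Tat, tyrosine aminotransferase, rose from 283 ± 6.61 to 1163 ± 271 RPKM, and the urea cycle genes Arg1, Ass1 and Cps1 rose by 1.09, 1.61 and 0.98. Glucose and insulin-response genes rose for 6 of 27, and for 6 adjusted over the list alone (0.36; 0.000163; adjusted p = 0.252 with an estimated correlation), among them Ppargc1a (0.94), Lpin2 (1.27) and Pygl (0.61). Interferon-response genes fell for 6 of 27 and for 13 adjusted over the list alone, with a median of -0.49 (1.20e-07; adjusted p = 0.411 with an estimated correlation). Tap1, Irf9, Rtp4 and Ifit1 differed by -1.29, -1.53, -0.84 and -0.98. Acute-phase genes fell for 4 of 26 and for 5 adjusted over the list alone (-0.12; 0.0280; adjusted p = 0.538 with an estimated correlation). Saa1, a serum amyloid, fell from 60.8 ± 30.1 to 5.70 ± 0.367 RPKM, with Saa2, Saa4 and Serpina3n at -2.95, -1.20 and -0.64.

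Oxidative phosphorylation genes rose for 12 of 75 and for 20 adjusted over the list alone (median 0.18, camera adjusted p = 9.82e-09; adjusted p = 0.531 with an estimated correlation), with Ndufa12, Ndufa8, Atp5h and Atp5o between 0.47 and 0.63. Ribosomal protein genes rose for 6 of 73 and for 10 adjusted over the list alone (0.32; 2.68e-12; adjusted p = 0.531 with an estimated correlation), among them Rpl24, Rps23, Rps7 and Rps4x. Xenobiotic metabolism genes rose for 4 and fell for 2 of 45, and for 5 and 2 adjusted over the list alone (0.35; 0.0219; adjusted p = 0.538 with an estimated correlation), with Cyp2c39, Cyp2b10, Sult1d1 and Fmo1 higher by 0.45 to 1.59. Macrophage markers had a median of -0.57 (0.00363) and pancreas markers of 2.54 (0.00488), with no member called in either list, and adjusted p = 0.552 and 0.605 with an estimated correlation. The remaining larger changes were of Chrna4 (2.79), Ppp1r3g (2.73) and the bile acid 12-alpha hydroxylase Cyp8b1, which fell from 243 ± 91.5 to 21.7 ± 7.50 RPKM. Repin1 also passed, but it was listed at 0 in LF 1, 2 and 3 and at 6.09, 5.36 and 4.93 RPKM in LF+CR, and its difference fell to 0.19 with its RefSeq transcripts summed. Genes reported whatever their result and not passing were Scd1 (1.01), Cyp7a1 (-0.64), Pck1 (0.80), G6pc (-0.02), Cyp4a14 (-0.72), Cd36 (-0.46), Pparg (0.63), Cyp2b9 (1.53), Cyp3a11 (0.38), Hspa5 (-0.14), Per2 (0.74) and Sirt1 (0.60).

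In LF+CR against LF, 215 genes passed without the pancreas libraries, 83 higher and 132 lower, 739 without the bile duct libraries, 408 higher and 331 lower, and 863 without LF 3, 326 higher and 537 lower. Leaving out LF 1, LF+CR 1 or LF+CR 2 gave 269, 250 and 304 genes, and the LF and LF+CR libraries fitted alone gave 200.

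HF+CR was compared with HF to ask what CR did on the HF diet. Of 20 lipid droplet genes 4 were called, all lower: Cidea, a lipid droplet fusion protein, fell from 55.0 ± 15 to 0.270 ± 0.174 RPKM, Cidec fell from 64.6 ± 17.2 to 6.70 ± 9.85 RPKM, and the droplet coat gene Plin4 fell from 30.3 ± 6.31 to 1.94 ± 0.995 RPKM. Of 25 cholesterol genes 7 rose, with Cyp51 going from 12 ± 2.48 to 43.5 ± 23.7 RPKM. Among the sex-biased genes called here, Slco1a1, an organic anion transporter of male liver, rose from 1.36 ± 1.26 to 62.8 ± 45.5 RPKM, and Cyp2b13 fell from 11.8 ± 6.20 to 0.0915 ± 0.141 RPKM, each against its direction on LF. limma called 145 genes at an adjusted p under 0.05, 65 higher and 80 lower, with 1447 at an unadjusted p under 0.05.

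Of 20 lipid droplet genes 4 fell over all genes and 11 adjusted over the list alone, with a median log2 difference of -0.65 (camera adjusted p = 4.12e-10; adjusted p = 0.170 with an estimated correlation). Cidea (NM_007702, chromosome 18, 67343564 to 67367794) differed by -5.44 ± 1.0 (adjusted p = 0.0187), Cidec (NM_178373, chromosome 6, 113424634 to 113435760) by -3.92 ± 0.82 (0.0313), Plin4 by -3.44 ± 0.51 (0.00539) and Mogat1, a monoacylglycerol acyltransferase, by -2.13 ± 0.44 (0.0295). Of 25 cholesterol genes 7 rose over all genes and 18 adjusted over the list alone, with a median of 1.15 (1.20e-16; adjusted p = 0.243 with an estimated correlation). Lss, Sc5d, Cyp51 and Insig1 rose by 1.33, 1.01, 1.61 and 1.51. Of 35 fatty acid oxidation genes 4 fell over all genes and 12 adjusted over the list alone, with a median of -0.40 (4.01e-13; adjusted p = 0.243 with an estimated correlation), namely Pex11a (-1.38), Acot4 (-1.21), Acot3 (-2.42) and Hadh (-0.44). Cholesterol genes passing over all genes numbered 0 without the pancreas libraries and 20 without the bile duct libraries. The mean of this list was 1.21, 1.49 and 0.29 in HF+CR 1, 2 and 3 and -0.20 to 0.06 in HF, so it was higher under CR without HF+CR 1 as well.

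Of 26 male-biased genes 4 rose over all genes and 11 adjusted over the list alone, with a median of 1.12 (camera adjusted p = 4.12e-10; adjusted p = 0.254 with an estimated correlation). Serpina1e, an alpha-1 antitrypsin, rose from 124 ± 159.6 to 2471 ± 1768 RPKM, and Slco1a1, Selenbp2 and C8b rose by 4.39, 3.06 and 1.65. Of 21 female-biased genes 3 fell over all genes and 5 adjusted over the list alone, with a median of -0.66 (1.97e-07; adjusted p = 0.170 with an estimated correlation): Cyp2b13 (-3.43), Acot3 (-2.42) and Slc22a27 (-1.69). HF+CR 3, the library with the highest cholangiocyte markers, had a male-biased mean of 0.02 against 2.13 and 1.27 in HF+CR 1 and 2. Male-biased genes passing over all genes numbered 1 without the pancreas libraries and 10 without the bile duct libraries, and female-biased ones 1 and 5. Enho, Clec2h, Cdh1 and Slc22a28 rose by 1.95 to 2.56, and Cyp2a22, Wfdc2 and Lgals1 fell, with log2 differences of -3.58, -2.92 and -2.61.

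Xenobiotic metabolism genes fell for 5 of 45, and for 6 with 2 higher adjusted over the list alone (median -0.16, camera adjusted p = 0.0335; adjusted p = 0.666 with an estimated correlation), among them the xenobiotic receptor Nr1i3 (-1.0), Fmo1 (-0.73), Cyp2c38 (-1.89) and Cyp2c39 (-1.22). Acute-phase genes fell for 2 of 26, Orm3 (-1.98) and Lbp (-0.89), and for 5 with 3 higher adjusted over the list alone (-0.32; 0.00674; adjusted p = 0.437 with an estimated correlation). Amino acid catabolism genes rose for 4 and fell for 1 of 32, over all genes and adjusted over the list alone (0.16; 0.0467; adjusted p = 0.808 with an estimated correlation): Cps1, Cbs, Tat and Agxt rose by 0.78 to 1.03. Interferon-response genes had a median of -0.49 with 0 of 27 called by limma over all genes and 4 lower adjusted over the list alone (2.40e-08; adjusted p = 0.387 with an estimated correlation). Camera also called class II genes (median -0.74, adjusted p = 0.0177) and macrophage markers (-0.37, 0.0467) lower and pancreas markers higher (1.45, 0.0442), with no member called by limma and adjusted p = 0.666, 0.808 and 0.808 with an estimated correlation. Medians of the other lists that camera called without a member called by limma were -0.11 for oxidative phosphorylation, 0.08 for ribosomal proteins, -0.14 for immediate early genes, 0.16 for endoplasmic reticulum stress genes and 0.17 for microRNA biogenesis, with adjusted p = 0.808, 0.819, 0.387, 0.808 and 0.254 in this order with an estimated correlation. Among 104 chromatin modifiers only Kdm5b passed over all genes (0.46) and none adjusted over the list alone, with a median of 0.15 (3.25e-05; adjusted p = 0.597 with an estimated correlation). Among the genes reported whatever their result, Cidec alone passed; the others were Scd1 (-0.86), Fasn (0.83), Sqle (1.65), Cyp7a1 (0.09), Pck1 (-0.12), G6pc (-0.47), Cyp4a14 (-0.82), Cd36 (-1.65), Pparg (0.45), Cyp2b9 (-2.36), Cyp3a11 (-0.90), Saa1 (-1.43), Hspa5 (0.01), Per2 (-0.51) and Sirt1 (0.02).

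In HF+CR against HF, 28 genes passed without the pancreas libraries, 7 higher and 21 lower, and 390 without the bile duct libraries, 150 higher and 240 lower. Leaving out 1 library also moved the higher and lower counts, to 14 higher and 44 lower without HF 1, 3 and 9 without HF 2, 9 and 26 without HF 3, 9 and 17 without HF+CR 1, 7 and 23 without HF+CR 2 and 123 and 173 without HF+CR 3. The HF and HF+CR libraries fitted alone gave 29 genes and array weights 668.

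Between the diets, 18 genes rose under CR on both LF and HF (1.96 were expected if the calls were independent) and 24 fell on both (2.79 expected), while 7 rose on LF and fell on HF (2.41 expected) and 4 fell on LF and rose on HF (2.27 expected). The 2 comparisons share 1 estimate of spread per gene, so their calls are not independent and the expected counts may be too low. The genes that rose on both included Insig1, Cyp51, Lss, Dhcr7, Sc5d and Mvk of the cholesterol list with Cps1 and Tat, and those that fell on both included Cidec, Pex11a, Nr1i3 and Wfdc2. The genes with opposite calls were Cyp2b13, Slc22a27, Cyp2c39, Fmo1, Glrx, Postn and Lrrc28, higher on LF, and Slco1a1, C8b, Srd5a1 and Fbxo21, lower on LF. These genes were picked out from the overlap after their values were seen. Slco1a1 differed by -3.45 on LF and 4.39 on HF. Across the 10356 genes, which are not independent replicates, the CR differences on the 2 diets correlated at r = 0.211 and rho = 0.284. The genes called in the same direction on both diets numbered 42, against 5 without the pancreas libraries, 18 with no filter on low values and 123 with array weights. Without LF 1, LF+CR 1 or LF+CR 2 they numbered 24, 22 and 21, without HF 1, HF 2 or HF 3 they numbered 9, 2 and 9, and without HF+CR 1, HF+CR 2 or HF+CR 3 they numbered 10, 6 and 64.

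The CR by diet interaction asked whether the CR difference itself differed between HF and LF. limma called 106 genes, 60 with a more positive and 46 with a more negative CR difference on HF, and 1220 at an unadjusted p under 0.05. Male-biased genes stood out as more positive on HF, with 12 of 26 called over all genes, 20 adjusted over the list alone and a median of 3.12 (camera adjusted p = 6.47e-28; adjusted p = 0.0376 with an estimated correlation). Female-biased genes were more negative, with 8 of 21 called over all genes, 13 adjusted over the list alone and a median of -2.61 (1.62e-21; adjusted p = 0.00235 with an estimated correlation). Cyp2b13 had the smallest adjusted p, with an interaction of -7.90 ± 0.57 (adjusted p = 4.30e-06) from 4.48 on LF and -3.43 on HF. C8a (NM_146148, chromosome 4, 104815679 to 104876487) differed by 4.79 ± 0.43 (5.01e-05), from -3.88 on LF and 0.91 on HF, and Cyp4a12a by 5.46 ± 0.76 (0.00307), from -4.68 and 0.78. Cux2 (-2.64) and Slc22a26 (-2.61) were female-biased genes that passed on LF only, with CR differences of 0.01 and -0.16 on HF, and Clec2h (2.94) passed on HF only. Cux2 was near the floor of the RPKM scale in both HF and HF+CR, so a fall on HF could not have been seen. Fbxo21, an F-box protein, differed by 1.37 and Cyp2c39 by -2.45.

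Camera called 7 further lists in the interaction. Fatty acid synthesis genes were more negative on HF (median -0.84, adjusted p = 2.02e-07; adjusted p = 0.456 with an estimated correlation), with 0 of 25 called by limma over all genes and 10 adjusted over the list alone. The medians were -0.27 for oxidative phosphorylation, -0.23 for ribosomal proteins, -0.49 for glucose and insulin-response genes, -0.51 for xenobiotic metabolism, -0.26 for amino acid catabolism and 0.13 for chromatin modifiers, all with an adjusted p of 0.400 or more with an estimated correlation. The ribosomal median changed sign without the pancreas libraries (0.02). Without the pancreas libraries 37 genes passed the interaction, 7 of them male-biased and 6 female-biased, and without the bile duct libraries 270, with 19 and 8. The count was 64 without LF+CR 1, 53 without HF 2, 60 without HF 3, 45 without HF+CR 1 and 211 without HF+CR 3, while the libraries of the 4 groups fitted alone gave 65 and array weights 181.

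**Figure D3:**
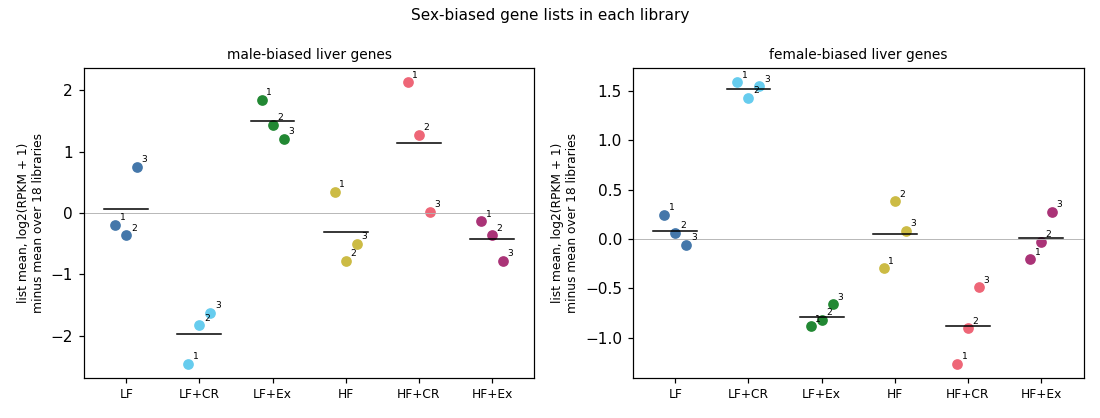
Mean log2(RPKM + 1) of the tested male-biased and female-biased liver genes in each library, minus the mean over the 18 libraries, by group; points are libraries numbered 1 to 3 and black lines are group means. Male-biased genes lay between -2.45 and -1.62 in LF+CR and between 0.02 and 2.13 in HF+CR, and female-biased genes between 1.43 and 1.59 in LF+CR and between -1.26 and -0.49 in HF+CR.

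**Figure D4:**
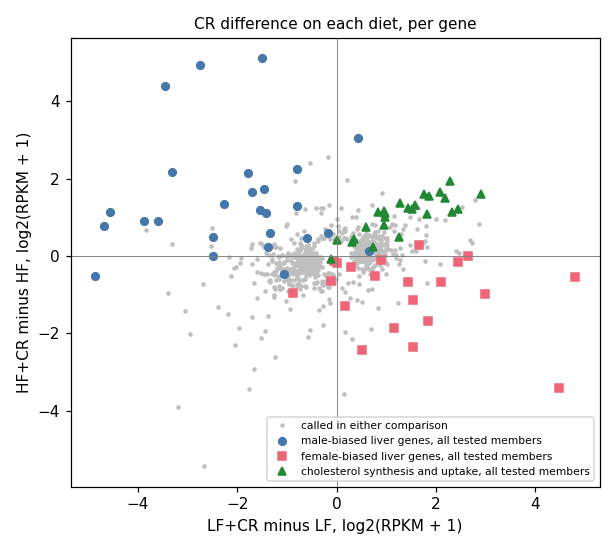
Log2(RPKM + 1) difference of LF+CR minus LF (x axis) against HF+CR minus HF (y axis), 1 point per gene; grey points are genes called in either comparison, blue circles male-biased, red squares female-biased and green triangles cholesterol synthesis and uptake genes, all tested members. The cholesterol genes had medians of 1.28 and 1.15 on the 2 axes, the male-biased genes -1.63 and 1.12, and the female-biased genes 1.43 and -0.66.

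HF+CR was compared with LF+CR to ask how the diets differed under CR. Of 26 male-biased genes 20 were called higher in HF+CR, and of 21 female-biased genes 15 lower. Serpina1e was at 2471 ± 1768 against 8.23 ± 7.63 RPKM, C8a at 171 ± 18.6 against 6.80 ± 3.19 RPKM and Mup20 at 4914 ± 2131 against 297 ± 180.2 RPKM. Elovl6, a fatty acid elongase, was at 10.5 ± 3.83 against 58.0 ± 25.5 RPKM. limma called 1013 genes, 487 higher and 526 lower, and 2726 at an unadjusted p under 0.05. Adjusted over the list alone, 23 male-biased genes rose and 1 fell, with a median of 3.0 (camera adjusted p = 2.22e-20; adjusted p = 0.105 with an estimated correlation). Serpina1e rose by 8.14 ± 0.97 (adjusted p = 0.000166), C8a by 4.56 ± 0.30 (7.64e-07), Mup20 by 4.10 ± 0.44 (7.70e-05) and C6 by 3.50 ± 0.36 (6.85e-05), with Mup1, Hsd3b5, Slco1a1 and Elovl3 higher by 4.43 to 5.95; Mup11 and Mup12, outside the list, rose by 4.92 and 4.88. Of the female-biased genes 17 fell adjusted over the list alone, with a median of -2.45 (2.57e-16; adjusted p = 0.00816 with an estimated correlation). Cux2, Slc22a26, Cyp2b13 and Fmo2 differed by -2.91, -3.40, -4.85 and -3.37, and Cyp2a4, Acot3 and Cyp2b9 by -6.42, -3.97 and -3.41.

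Interferon-response genes rose for 10 of 27 and for 13 adjusted over the list alone, with a median of 0.68 (camera adjusted p = 1.27e-08; adjusted p = 0.436 with an estimated correlation): Tap1 (1.51), Rtp4 (1.03), Irf9 (1.43) and Psmb9 (1.51). Fatty acid synthesis genes fell for 11 of 25 and for 14 adjusted over the list alone, with a median of -0.91 (5.31e-06; adjusted p = 0.436 with an estimated correlation): Me1 (-2.14), Pnpla3 (-1.75), Elovl6 (-2.29) and Tkt (-0.91). Oxidative phosphorylation genes fell for 21 of 75 and for 41 adjusted over the list alone, with a median of -0.35 (3.67e-16; adjusted p = 0.419 with an estimated correlation), and Ndufa12, Ndufa8, Sdhd and Ndufv1 differed by -0.63 to -0.51. Xenobiotic metabolism genes fell for 12 and rose for 3 of 45, and for 20 and 4 adjusted over the list alone (-0.49; 4.12e-05; adjusted p = 0.412 with an estimated correlation): Fmo1, Cyp2c39, Cyp2c38 and Ces1d differed by -2.62 to -1.06. Glucose and insulin-response genes fell for 6 of 27, and for 14 with 1 higher adjusted over the list alone (-0.52; 4.06e-05; adjusted p = 0.335 with an estimated correlation), among them Pck1, the gluconeogenic PEP carboxykinase (-1.60), Ppargc1a (-0.79) and Klf15 (-0.62). Amino acid catabolism genes fell for 9 and rose for 3 of 32, and for 11 and 3 adjusted over the list alone (-0.29; 0.0154; adjusted p = 0.616 with an estimated correlation), with Tat, Arg1, Asl and Mat1a at -1.69 to -0.66.

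Ribosomal protein genes fell for 8 of 73 and for 17 adjusted over the list alone (-0.37; camera adjusted p = 9.54e-12; adjusted p = 0.616 with an estimated correlation), with Rpl23, Rpl8, Rpl7a and Rpl21 at -0.63 to -0.44. Class II genes rose for 1 of 6, H2-DMa (1.06), and for 6 adjusted over the list alone (1.17; 0.00236; adjusted p = 0.616 with an estimated correlation). Camera also called circadian clock genes lower (-0.52), with Cry1 at -0.89, and lymphocyte markers higher (0.65), with Cd79b at 1.02; macrophage markers (0.66) and stellate cell genes (0.65) were called higher with no member passing. These 4 lists had an adjusted p of 0.616 with an estimated correlation. Without the bile duct libraries the stellate cell call (adjusted p = 0.106) and the lymphocyte call (0.186) were lost. Lpgat1 also passed, but it was listed at 0 in HF+CR 1, 2 and 3 and at 20.6, 26.7 and 18.6 RPKM in LF+CR. Leaving out the pancreas libraries gave 131 genes, 74 higher and 57 lower, 9 of them male-biased and 10 female-biased. The count was 482 without LF+CR 1, 613 without LF+CR 2, 430 without HF+CR 1 and 638 without HF+CR 2, and it was 380 with the compared libraries fitted alone and 2238 with array weights.

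LF+Ex was compared with LF, and HF+Ex with HF, to ask what Ex did on each diet. No single gene passed in either comparison. On LF camera called male-biased genes higher and female-biased genes lower: the medians were 1.13 (camera adjusted p = 6.78e-35; adjusted p = 0.0332 with an estimated correlation) and -0.50 (0.00123; adjusted p = 0.354 with an estimated correlation). Neither list was called by fry, which tests a list without comparing it with other genes (adjusted p = 0.135 and 0.0610). None of the 26 or 21 members passed over all genes, and 5 higher and 5 lower passed adjusted over the list alone. In the same comparison camera called pancreas markers higher (median 0.44, 11 of 11 positive, adjusted p = 0.00274; adjusted p = 0.961 with an estimated correlation). Stellate cell genes were called lower (-0.43, 0 of 19 positive, 0.0438; adjusted p = 0.991 with an estimated correlation). No member of either list passed. LF+Ex 1, a pancreas library, had the highest male-biased mean of its group, at 1.84 against 1.44 and 1.21 in LF+Ex 2 and 3. limma called 0 genes for LF+Ex against LF with 944 at an unadjusted p under 0.05, and 0 for HF+Ex against HF with 377. The 5 genes with the smallest unadjusted p on LF did not pass: Cyp2b9 was at 4.98 ± 7.59 against 69.7 ± 14 RPKM with a log2 difference of -4.40 ± 0.74 (adjusted p = 0.243), Slc22a27, Slc22a26 and Cyp2a22 differed by -1.92, -1.30 and -2.40, and Glrx3 by -0.57. On HF they were Tmem238 (-1.02, adjusted p = 0.292), H2-Ke6 (-0.48), Xpa (-0.67), Dis3l2 (0.71) and Rab5if (-0.43), none passing.

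In LF+Ex against LF, amino acid catabolism genes had a median of 0.26 (camera adjusted p = 7.35e-16; adjusted p = 0.102 with an estimated correlation), proteasome genes of -0.18, fatty acid oxidation genes of -0.29, antioxidant genes of -0.36 and glucose and insulin-response genes of 0.01 (adjusted p = 0.932, 0.979, 0.991 and 0.198 in this order with an estimated correlation). The median of all genes was -0.13 in this comparison and 0.00 under either scaling, and the camera calls of proteasome and circadian clock genes were lost under median-of-ratios scaling (adjusted p = 0.180 and 0.616). Camera called acute-phase, oxidative phosphorylation, circadian clock and bile acid genes higher relative to the other genes although their medians were -0.06, -0.06, -0.01 and -0.05 (adjusted p = 0.924, 0.991, 0.961 and 0.453 in this order with an estimated correlation), and these medians turned positive under median-of-ratios scaling. Of the 13 lists called, only the male-biased list kept its call with an estimated correlation. In HF+Ex against HF camera called 12 lists, each at adjusted p = 0.70 with an estimated correlation. Markers of other cells were among them, with medians of 0.21 for macrophages, 0.13 for stellate cells and 0.12 for endothelial cells. The other medians were -0.37 for cholesterol genes, -0.19 for fatty acid oxidation, -0.13 for ribosomal proteins, -0.11 for proteasome, -0.11 for oxidative phosphorylation, 0.04 for chromatin modifiers, 0.10 for the interferon response, 0.10 for endoplasmic reticulum stress and 0.15 for heat-shock proteins, at the same adjusted p = 0.70 with an estimated correlation. The Ex by diet interaction gave 0 genes with limma and 525 at an unadjusted p under 0.05. Its 5 genes with the smallest p, Akr1b3 (2.41), Atp6v0c (1.93), Ppp2r5c (-0.87), Adrb3 (-1.16) and Zfp672 (2.67), each had an adjusted p of 0.693, and Ppp2r5c changed sign with RefSeq transcripts summed. In that interaction camera called 13 lists. Male-biased genes had a median of -1.09 (camera adjusted p = 1.21e-15; adjusted p = 0.224 with an estimated correlation). Stellate cell genes had a median of 0.64 (18 of 19 positive, 0.00462; adjusted p = 0.881 with an estimated correlation). Endothelial markers had one of 0.34 (13 of 14 positive, 0.00754; adjusted p = 0.881 with an estimated correlation). The medians of the other 10 lists were 0.54 for female-biased, 0.42 for antioxidant, 0.42 for heat-shock, 0.18 for chromatin modifier, -0.32 for amino acid catabolism, -0.25 for glucose and insulin-response, -0.20 for cholesterol, -0.08 for bile acid, -0.08 for oxidative phosphorylation and -0.04 for ribosomal protein genes, all with an adjusted p of 0.224 or more with an estimated correlation. Single settings gave 1 to 4 genes in these 3 tests: LF+Ex against LF gave 4 without LF+Ex 3, 2 with a pseudocount of 0.1, 2 with array weights and 1 with its libraries alone, and HF+Ex against HF gave 1 without HF 1, 1 without LF 3 and 1 with array weights. The Ex by diet interaction gave 1 gene without HF 1, 1 without the pancreas libraries and 1 with its libraries alone.

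HF+Ex was compared with LF+Ex to ask how the diets differed under Ex. The called genes included 15 of the interferon response, 5 of class II antigen presentation and 4 macrophage markers that were higher in HF+Ex, and 8 male-biased genes that were lower. Lcn2, the acute-phase lipocalin, rose from 9.20 ± 12.2 to 132 ± 76.0 RPKM, Ubd, an interferon-induced ubiquitin-like protein, rose from 0.665 ± 1.01 to 25.4 ± 12.7 RPKM, and Ccl2, a monocyte chemokine, rose from 0.0877 ± 0.152 to 3.25 ± 1.07 RPKM. Cidea rose from 9.70 ± 16.1 to 56.4 ± 13.4 RPKM, and Hsd3b5, a steroid dehydrogenase of male liver, fell from 61.6 ± 34.6 to 0.0890 ± 0.113 RPKM. limma called 533 genes, 428 higher and 105 lower, and 2301 at an unadjusted p under 0.05. Of 27 interferon-response genes 15 rose over all genes and 21 adjusted over the list alone, with a median of 0.93 (camera adjusted p = 1.02e-11; adjusted p = 0.354 with an estimated correlation). Gbp2 rose by 1.93 ± 0.30 (adjusted p = 0.00549), Cxcl9 by 1.97 ± 0.35 (0.00945) and Tap1 by 1.01 ± 0.18 (0.00945). Class II genes rose for 5 of 6 and for 6 adjusted over the list alone, with a median of 1.77 (3.42e-05; adjusted p = 0.390 with an estimated correlation): H2-Eb1, H2-Aa, H2-DMb1 and H2-DMa rose by 1.25 to 1.93. Macrophage markers rose for 4 of 19, Ccl2, Cd5l, Itgax and Ctss, and for 14 with 1 lower adjusted over the list alone (1.08; 0.00196; adjusted p = 0.598 with an estimated correlation).

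Of 26 male-biased genes 8 fell over all genes and 16 adjusted over the list alone, with a median of -1.40 (camera adjusted p = 1.09e-16; adjusted p = 0.354 with an estimated correlation): Cyp4a12b (-3.83), Slco1a1 (-4.52), C8b (-1.66) and Hsd3b5 (-5.64), with Mup7, Serpina1e, Mup21 and Elovl3 between -5.07 and -2.80. Without the pancreas libraries 1 of them passed, although the list mean was still 1.44 and 1.21 in LF+Ex 2 and 3 against -0.77 to -0.13 in HF+Ex. Of 21 female-biased genes 4 rose over all genes, and 8 with 1 lower adjusted over the list alone (0.47; 0.0447; adjusted p = 0.598 with an estimated correlation): Cyp2b9 rose from 4.98 ± 7.59 to 91.4 ± 19.5 RPKM, and Cyp2b13, Slc22a27 and Hao2 rose by 3.40, 2.20 and 1.55. Lipid droplet genes rose for 3 and fell for 1 of 20, and for 7 and 2 adjusted over the list alone (0.77; 0.0447; adjusted p = 0.688 with an estimated correlation): Cidea, Mogat1 and Vldlr rose by 3.90, 1.85 and 0.77. Cell cycle genes rose for 2 of 10, the replication genes Mcm2 (0.81) and Mcm3 (0.65), and for 3 adjusted over the list alone (0.41; 0.0341; adjusted p = 0.598 with an estimated correlation). The female-biased, lipid droplet and cell cycle calls were lost without the pancreas libraries (adjusted p = 0.0865, 0.0905 and 0.0608). LF+Ex 1, the pancreas library among these groups, had list means of -0.89, -0.33 and -0.24. In LF+Ex 2 and 3 they were -0.82 and -0.66, -0.76 and 0.36, and -0.13 and -0.37. The lost calls therefore do not show that these differences rest on LF+Ex 1. Stellate cell genes rose for 1 of 19, Lrat (0.81), and for 7 adjusted over the list alone (0.75; 0.000259; adjusted p = 0.598 with an estimated correlation). Orm3 and Saa2 rose by 3.33 and 2.99.

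Among genes of glucose metabolism 3 of 27 fell, over all genes and adjusted over the list alone (-0.22; camera adjusted p = 0.000443; adjusted p = 0.354 with an estimated correlation): Pfkfb3 (-1.79), Pck1 (-1.46) and Igfbp2 (-1.59). Amino acid catabolism genes fell for 2 and rose for 1 of 32, and for 4 and 1 adjusted over the list alone (-0.35; 7.39e-09; adjusted p = 0.354 with an estimated correlation), with Tat and Cps1 at -1.11 and -0.91. Camera called antioxidant genes higher (0.41) and ribosomal proteins (-0.18) and oxidative phosphorylation genes (-0.13; Cox7a2 at -0.43) lower, with adjusted p = 0.707, 0.598 and 0.598 in this order with an estimated correlation. Fatty acid oxidation genes were called lower (-0.03; adjusted p = 0.707 with an estimated correlation), with Cyp4a32 at -1.05 and Acot1 at -1.89 lower and Hadh (0.46) higher, and adjusted over the list alone 1 was higher and 4 lower. The oxidative phosphorylation and fatty acid oxidation calls were lost under quantile normalization (adjusted p = 0.143 and 0.701). The bile acid list was called lower (adjusted p = 0.354 with an estimated correlation) with a median of 0.02 and a mean of -0.21, a median that turned negative under both scalings. Alb, serum albumin, passed here, but it was listed at 0 in 14 libraries, LF+Ex among them, and at 30803, 33167 and 33218 RPKM in HF+Ex 1, 2 and 3 and 30395 RPKM in HF 1. Without the pancreas libraries 33 genes passed and without the bile duct libraries 1114. The bile duct libraries belong to neither group, and the median difference of all genes was 0.0760 with and without them. That rise thus came from the estimate of spread shared by all groups and not from the differences. The count was 58 without LF+Ex 1, 82 without LF+Ex 2, 105 without HF+Ex 1, 102 without HF+Ex 2, 60 without HF+Ex 3 and 845 without HF+CR 3, and leaving out LF+Ex 3 gave 653 with 395 higher and 258 lower. Of the called genes 80.3% were higher as deposited, 60.5% without LF+Ex 3, 60.1% of 756 under median-of-ratios scaling and 52.9% of 720 under quantile normalization, and a mean of at least 5 RPKM gave 211 genes, the compared libraries alone 872 and array weights 2241.

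The 42 genes called in HF against LF were followed under CR and Ex, to ask how much of the diet difference was kept. A slope through the origin of HF+Ex minus LF+Ex on HF minus LF was 0.971 ± 0.0932 (jackknife SE over 6 libraries), and 41 of the 42 genes kept their sign. The slope of HF+CR minus LF+CR was -0.179 ± 0.0466, with 34 of 42 genes of the same sign, and this slope was carried by Cyp2b13 and Cyp4a12b. The jackknife held the 42 genes and their HF minus LF differences fixed. Its errors thus leave out the spread of the HF and LF libraries and the choice of genes, and they are too small. Cyp2b13 differed by 3.06 in HF against LF, 3.40 under Ex and -4.85 under CR, and Cyp4a12b by -2.78, -3.83 and 2.72. Without these 2 genes, left out after seeing the data, the slopes were 0.313 ± 0.0725 under CR and 0.857 ± 0.125 under Ex. The median ratio per gene was 0.293 under CR and 0.732 under Ex over all 42 genes. The difference of the slopes, CR minus Ex, was -1.15 (two-sided exact permutation test, p = 0.005, the smallest that 400 assignments can give), and -0.544 without Cyp2b13 and Cyp4a12b (exact p = 0.045). Under CR the slope changed sign to 0.284 with median-of-ratios scaling, 0.308 with quantile normalization, 0.119 without the bile duct libraries, 0.0344 without LF 2 and 0.0765 without HF+CR 3, and it was -0.0876 without LF 3, -0.438 without LF+CR 2, -0.626 without HF 1, -1.07 without HF 2, -0.323 without HF 3 and -0.372 without HF+CR 2. The difference stayed negative in every setting run, at -0.530 with median-of-ratios scaling, -0.471 with quantile normalization and -2.09 without HF 2, and no slope could be computed without LF 1, where no gene passed in HF against LF.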

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

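In this part the tests on animals of the other sex, on the share of hepatocytes and on pancreas tissue, and all counts over splits of the libraries, were chosen only after the result was seen.

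The test of the difference between the CR effects on HF and LF singled out 106 genes, the 8 named ones and both lists of sex-biased genes. The interactions on the log2 scale were -7.90 for Cyp2b13, 4.79 for C8a, -2.64 for Cux2, 1.37 for Fbxo21, -2.61 for Slc22a26, 2.94 for Clec2h, 5.46 for Cyp4a12a and -2.45 for Cyp2c39. The median interaction was 3.12 for male-biased and -2.61 for female-biased genes.

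The opposite CR response of sex-biased genes on the 2 diets was weighed against 3 technical explanations. The tests on library scaling and on other tissue used the mean interaction, which a response on LF alone can carry. Animals of the other sex in some groups are argued against by the Y-linked gene Ddx3y, which was at 5.95 RPKM or more in all 18 libraries, where Xist reached 0.0184 RPKM at most. Library scaling as the whole cause is argued against because at least 98.7% of the mean interaction of both lists was kept under either scaling. Median-of-ratios scaling moves all genes of a library 1 way and could not move 2 lists apart, so its result was set in advance. For other tissue or cell types, at least 78.8% was kept without the pancreas or the bile duct libraries. The male-biased mean was 3.48 ± 0.82 with all libraries and 2.74 ± 0.80 without the pancreas libraries. This argues only against either set alone as the whole cause of the interaction. HF+CR 1 and HF+CR 3 were never left out together, so other tissue as a cause of the response on HF is left open. Male-biased means in HF+CR 1, 2 and 3 were 2.13, 1.27 and 0.02, against -0.78 to 0.34 in HF. Female-biased means were -1.26, -0.90 and -0.49, against -0.30 to 0.38. Over splits of the libraries 6 of 100 gave at least the real 106 genes, with 744 in the highest other split, which points to a structure of the samples: the 5 others turn the contrast towards a sum of both CR effects and so do not show what chance gives, the 53 splits that do not reached 89 at most, and since this division was made after seeing the counts the splits leave open whether chance can be excluded. No biological explanation of the pattern was tested.

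HF+CR 3 stood apart from HF+CR 1 and 2. A sample of HF or HF+Ex under a wrong label was tested on 296 genes, called between HF+CR 1 and 2 and the HF libraries. On a scale from HF (0) to HF+CR 1 and 2 (1), HF+CR 3 lay at 0.365. The 6 HF and HF+Ex libraries lay at -0.146 to 0.0923. The HF libraries helped to pick the genes and set the 0, so they lie near it in part by construction. The HF+Ex libraries did neither and lay at -0.0443 to -0.0184, which argues against a sample of HF+Ex under a wrong label. For a sample of HF the test is weaker. A wrong label of another kind cannot be told apart from a real difference: the deviations of HF+CR 3 correlated at -0.0132 with the other HF+CR libraries and at 0.224 with HF+Ex, a gap of -0.237, while the single libraries closest to it were LF 2 (0.247), the other library with raised bile duct markers, and HF 2 (0.237), and on the scale above LF 3 (0.466), LF+CR (0.359 to 0.377) and LF+Ex 3 (0.319) lay near HF+CR 3. The rises of 5 marker lists were 1.58 for cholangiocyte, 1.15 for stellate cell, 1.05 for lymphocyte, 0.86 for macrophage and -0.01 for endothelial markers. The largest and smallest, picked from these same values, differed by 1.59, against an SD of 0.356. This argues only against a lower share of hepatocytes that raises all other cell types alike. A lower share with an unequal rise of other cells is left open, since all lists but the endothelial one rose. No biological explanation was tested, since the labels give nothing that sets this library apart.

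Pancreas transcripts stood in LF+CR 1, HF+CR 1 and LF+Ex 1. A candidate source is pancreas tissue carried over with the liver. All 11 tested markers lay above the other 15 libraries in both LF+CR 1 and HF+CR 1, and 10 in LF+Ex 1. This count was largely set in advance. Of 17 listed markers 11 passed the filter of at least 1 RPKM in at least 3 libraries, and 9 of these passed only through these 3 libraries. The libraries were also picked for such transcripts, so the count does not decide on the source. The ratio of LF+CR 1 to HF+CR 1 ran from 1.59 for Cela1 to 42.2 for Reg1, with a median of 7.36. Both ends are uncertain, since Cela1 was present in other libraries as well and Reg1 was at 1.11 RPKM in HF+CR 1. Whether 1 tissue in 1 proportion accounts for the markers is left open. Cela1 reached 38.4 RPKM in the other 15 libraries and Ctrb1 1.34 RPKM, and the other 9 markers stayed under 1 RPKM there. No biological explanation was tested, since these libraries fall in 3 groups.

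For the comparisons of 3 libraries with 3, the 10 splits are too few for a share under 0.05. HF against LF gave 42 genes in the real split, reached by 1 of 10, and 1 in the highest other split. LF+CR against LF gave 673 and HF+CR against HF 145, each reached by 1 of 10, with 1 in the highest other split, and HF+CR against LF+CR gave 1013, also reached by 1 of 10, with 1. HF+Ex against LF+Ex gave 533, reached by 1 of 10, with 0. For a real count of 0, as in LF+Ex against LF and HF+Ex against HF (10 of 10 splits each, with 4 and 1 genes in the highest other) and in the Ex by diet interaction (100 of 100 splits, with 6), every split reaches it whatever the data, so that these say nothing on chance.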

How the results depend on the processing

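Only after seeing the data were chosen the tests without Alb, without genes at 0 or at least 1 RPKM, without the pancreas libraries (LF+CR 1, LF+Ex 1, HF+CR 1), without the bile duct libraries (LF 2, HF+CR 3) and without Cyp2b13 and Cyp4a12b. Where the libraries left out belong to none of the compared groups, the differences of the genes stay as they were and only the shared estimate of spread changes. The cause of the other shifts below was not tested. Comparisons are written HF vs LF and so on, and the slopes are the diet difference kept under CR or Ex.

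A pseudocount of 0.1 gave 21 genes in HF vs LF, 2 in LF+Ex vs LF, and slopes of -0.283 under CR and 0.757 under Ex. No filter gave a CR slope of -0.132 and 18 genes shared between the CR effects. A mean of at least 5 RPKM gave 14 in HF vs LF, 211 in HF+Ex vs LF+Ex and a CR slope of -0.912. Median-of-ratios scaling gave 203 in HF vs LF and slopes of 0.284 and 0.815, and quantile normalization 283, 0.308 and 0.779, so that the CR slope changed sign under both. Robust moderation gave a CR slope of -0.0532 and summed transcripts -0.231. Array weights gave 668 in HF+CR vs HF, 2 in LF+Ex vs LF, 1 in HF+Ex vs HF, 2238 in HF+CR vs LF+CR, 2241 in HF+Ex vs LF+Ex, 181 in the CR interaction, slopes of -0.117 and 0.875 and 123 shared genes. The compared groups alone gave 0 in HF vs LF, 200 in LF+CR vs LF, 29 in HF+CR vs HF, 1 in LF+Ex vs LF, 380 in HF+CR vs LF+CR, 872 in HF+Ex vs LF+Ex, 65 in the CR interaction and 1 in the Ex interaction. The replicate block gave 14 in HF vs LF. In no comparison did all 3 same-numbered pairs of libraries correlate above 0.1 (0.0835, 0.316 and 0.242 in HF vs LF). In HF+Ex vs HF, however, all 3 libraries were closest to their own number (0.153, 0.0469 and 0.200). This held for 2 libraries in HF vs LF and in HF+CR vs LF+CR, and for 0 in the other comparisons. Whether the replicate numbers pair libraries is left open. The slopes were not run with the block or the groups alone.

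Leaving out the pancreas libraries gave 11 in HF vs LF, 215 in LF+CR vs LF, 28 in HF+CR vs HF, 131 in HF+CR vs LF+CR, 33 in HF+Ex vs LF+Ex, 37 and 1 in the CR and Ex interactions, slopes of -0.414 and 0.800 and 5 shared genes. Leaving out the bile duct libraries gave 140 in HF vs LF, 390 in HF+CR vs HF, 1114 in HF+Ex vs LF+Ex, 270 in the CR interaction and a CR slope of 0.119, of changed sign. Without Cyp2b13 and Cyp4a12b the CR slope changed sign to 0.313 and the Ex slope was 0.857. With all libraries of a comparison kept or the sets above left out, the difference of the slopes stayed negative, from -1.91 with a mean of at least 5 RPKM to -0.471 with quantile normalization.

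Camera called 10, 15, 18, 13, 12, 14, 15, 9 and 13 lists in HF vs LF, LF+CR vs LF, HF+CR vs HF, LF+Ex vs LF, HF+Ex vs HF, HF+CR vs LF+CR, HF+Ex vs LF+Ex and the CR and Ex interactions. In that order camera with an estimated correlation called 0, 0, 0, 1, 0, 1, 0, 2 and 0 lists, fry 0, 8, 6, 0, 0, 7, 5, 2 and 0, and camera with the replicate block 10, 15, 16, 10, 12, 12, 14, 9 and 15.

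With 1 library of the compared groups left out, counts ran over 0 to 40 in HF vs LF, 250 to 863 in LF+CR vs LF, 12 to 296 in HF+CR vs HF, 0 to 4 in LF+Ex vs LF, 0 to 1 in HF+Ex vs HF, 430 to 1231 in HF+CR vs LF+CR, 58 to 653 in HF+Ex vs LF+Ex, 45 to 211 in the CR interaction and 0 to 1 in the Ex interaction. The CR slope ran over -1.07 to 0.0765, the Ex slope over 0.709 to 1.05, their difference over -2.09 to -0.788 and the shared genes over 2 to 64. Without LF 1 no gene passed in HF vs LF and no slope was computed. A group left with 2 libraries is assumed to vary like the others.

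None of the named genes that were called changed sign in any setting, and other called genes were not followed. Without the bile duct libraries the uncalled named genes that did were Cyp7a1 (-0.27), Cyp3a11 (0.52) and Per2 (-0.17) in HF vs LF, G6pc (0.20) in LF+CR vs LF, and Hspa5 (-0.0578) and Sirt1 (-0.0312) in HF+CR vs HF. Summed transcripts turned Pparg in HF vs LF (0.78) and HF+CR vs HF (-0.88) and Ppp2r5c in the Ex interaction (0.0521). Array weights turned Cyp3a11 in HF vs LF (0.0935), G6pc in LF+CR vs LF (0.0863), and Cyp7a1 (-0.34) and Sirt1 (-0.24) in HF+CR vs HF. Without the pancreas libraries they were Cyp7a1 in LF+CR vs LF (0.0393) and Cyp7a1 (-0.32), Pck1 (0.0423) and Sirt1 (-0.23) in HF+CR vs HF, and with a pseudocount of 0.1 Sirt1 in HF+CR vs HF (-0.0163). With 1 library left out the ranges were, in HF vs LF, Cd36 -0.0345 to 0.47, Cyp3a11 -0.60 to 0.52, Cyp7a1 -0.27 to 0.33, G6pc -0.0747 to 0.32, Per2 -0.17 to 0.53; in HF+CR vs HF, Cyp7a1 -0.32 to 0.53, Hspa5 -0.0883 to 0.19, Pck1 -0.56 to 0.15, Sirt1 -0.23 to 0.32; in LF+CR vs LF, Cyp3a11 -0.0400 to 1.08, Cyp7a1 -1.11 to 0.0393, G6pc -0.26 to 0.34. Of 264 named differences, calls were lost in 19 with a pseudocount of 0.1, 40 without filter, 77 in the groups alone, 32 with the replicate block, 124 without the pancreas libraries and 14 without the bile duct libraries, and with 1 library left out in 460 of 1662 values. Both totals include uncalled differences, which could lose no call, so the share among called ones is higher.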

Other observations

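All tests on relations within groups in this part were chosen only after the results were seen.

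Genes of chromatin and microRNA pathways, named in the title of the series, showed few calls for single genes and small shifts of whole lists. Of 14 microRNA biogenesis genes limma called 1 lower in HF+CR against LF+CR and none in the other comparisons, and camera called the list only in HF+CR against HF, with a median log2 difference of 0.17 (camera adjusted p = 0.00160, and 0.254 with an estimated correlation). Of 104 chromatin modifiers limma called 1 lower in LF+CR against LF, 1 higher in HF+CR against HF, 2 higher and 1 lower in HF+CR against LF+CR, 1 higher in the CR by diet interaction and none elsewhere. Camera called this list lower in HF against LF (median -0.12, adjusted p = 0.00133) and higher in HF+CR against HF (0.15, 3.25e-05), HF+Ex against HF (0.04, 0.00561) and the CR and Ex interactions (0.13, 0.00185 and 0.18, 0.0257). With an estimated correlation none of these calls held, and the adjusted p was 0.998, 0.597, 0.70, 0.810 and 0.881 in that order.

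Single transcripts behaved unlike the rest of the liver profile. The RefSeq row NR_046233 ran from 0 RPKM in LF+Ex 3 and HF+Ex 1 to 10093 RPKM in HF+Ex 3, with no group at a level of its own. Alb was one of 16 genes listed at 0 in at least 3 libraries and at 1 RPKM or more in every other. Of these, 2 were called in LF+CR against LF, 2 in HF+CR against LF+CR and 1 in HF+Ex against LF+Ex.

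Within groups, the male-biased list was related to 6 other lists over the 18 libraries, each value taken as a deviation from its group mean and tested with 100000 permutations within groups. None of the 6 relations passed after Benjamini-Hochberg adjustment. With cholangiocyte markers it gave r = -0.654 (permutation p = 0.0895) and rho = -0.486 (permutation p = 0.117), with r = -0.411 without HF+CR 3 and LF 2. Macrophage markers gave r = -0.582 (permutation p = 0.0860) and rho = -0.441 (permutation p = 0.160), with r = -0.520 without LF 2 and HF 2. Acute-phase genes gave r = -0.598 (permutation p = 0.0805) and rho = -0.531 (permutation p = 0.0744), with r = -0.346 without HF+CR 3 and LF 3. Lipid droplet genes gave r = -0.583 (permutation p = 0.0320) and rho = -0.558 (permutation p = 0.0480), with r = -0.625 without LF+Ex 3 and LF 1. Antioxidant genes gave r = -0.741 (permutation p = 0.0393) and rho = -0.680 (permutation p = 0.0205), with r = -0.562 without HF+CR 3 and LF 2. Cholesterol genes gave r = 0.323 (permutation p = 0.495) and rho = 0.191 (permutation p = 0.556), with r = -0.123 without HF+CR 3 and LF 2. The adjusted p was 0.107 for the first 5 relations and 0.495 for cholesterol genes on r, and 0.123 or more on rho.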
